A study of Danio rerio with 92 samples.

How the data were processed

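Total RNA from pools of 24 whole zebrafish embryos, labelled as 48 hours post fertilization after 48 h of exposure in multiwell plates, was amplified and labelled with Cy3 and hybridised to Agilent single-colour arrays of design 019161, per the labels' protocols and the file headers. The deposited scanner files hold spot intensities made with Feature Extraction 9.5.1.1, per the file headers; the processed signal in them is the background-corrected intensity of that software, not scaled between arrays. The authors also deposited a value table on a log2 scale. Set against the scanner values it proved to be centred per probe within each experiment, with column medians from -0.04 to 0.10 and correlations with the values computed here from 0.578 to 0.997; what scaling the authors applied first is unknown. Its 2 columns for solvent control D of EE2 and flutamide are empty and were not used.

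The 92 files came from 88 distinct arrays on 23 slides of 3 to 4 arrays, scanned on 5 days. The 4 solvent controls of flutamide are the same arrays as those of EE2, a fact the design fixed beforehand had missed when it stated that no compounds share control arrays, so overlaps of this pair were set beside 100 simulations of unchanged groups and all 6 splits of the controls, over 26767 genes. Controls with the labels' solvent mark were taken as acetone controls and the others as water controls. No sample was left out.

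From the deposited intensity, log2 of the processed signal minus the array's 75th percentile was computed. The 1417 control spots per array and 1261 spots with outlier flags in all (652 probes; 2 to 115 spots per array) were left out, saturated spots (0 to 5 probes per array) were kept, and the spots of a repeated probe were averaged (50 of 43603 probes, up to 5 spots). Probes were named through accessions for 16075, Entrez identifiers for 2532, current symbols for 1046 and older symbols for 1446, and 22504 kept the name in the file. For each name the probe with the highest mean was taken, which left 35971 genes or unnamed probes, 13298 with a gene name. A gene entered a fit if its probe was well above background on at least 4 of the fit's arrays. Where a gene was well above background on no array of a group, the change is given as at least N-fold, the brighter group's mean against the higher of that probe's signal and the lowest signal well above background on each array of the dimmer group. Where only some arrays of a group measured it, their number is given with the fitted change.

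Each experiment's arrays were fitted together with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with group means and no covariate. EC20 and EC10 were each tested against control and against each other, solvent against water control where both existed, and the differences of the EC20 and EC10 responses between propanil and linuron and between propanil and flutamide. Tests were 2-sided, with Benjamini-Hochberg adjustment over the genes of a test and a threshold of 0.05, and intervals are at 95 percent. For propanil and linuron the solvent control was the reference. In total 35 gene lists were tested in the 14 comparisons with control by limma's camera with a preset correlation of 0.01, adjusted over the 490 tests, and again with estimated correlation, where 0 of the 133 calls held. For the lists named at EC20 the estimated correlation gave the highest adjusted p of the settings tried. The groups, tests, gene lists and most alternatives, and the rule for named genes were fixed before the data were examined.

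Genes were named by that rule, leaving out names that are only clone or locus identifiers. Per compound it took the 6 largest rises and 6 largest falls among calls at EC20 whose 4 exposed arrays all lay on one side of the 4 controls with EC10 in the same direction, and the next 2 each way at EC10. It added the 3 members with the smallest p in each of the 4 lists with the smallest camera p that held a call, and in every compound vtg1, cyp19a1b, esr1, cyp1a, cyp51, hsp70l, gstp1 and cyp3a65. Between compounds it took the 5 largest differences each way and the 10 genes called the same way in the most compounds.

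Whether replicate letters pair the samples was checked from the correlation of deviations from group means, with pairing taken where every same-letter pair was over 0.1. They paired in EE2 EC20 against control (r = 0.42 to 0.55), EC10 against control (0.16 to 0.67) and EC20 against EC10 (0.24 to 0.79), in flutamide EC20 against EC10 (0.11 to 0.48) and in propanil solvent against water (0.31 to 0.45), and in no other comparison. The labels do not say what a letter marks.

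The steps were tested on simulated arrays with 200 changed genes. At 2-fold and 4-fold changes, limma recovered 28.4 and 89.4 percent for EE2 (26993 genes), 41.8 and 84.8 for flutamide (27157 genes), 86.6 and 97.0 for bisphenol A (26780 genes), 88.1 and 98.5 for methylparaben (25071 genes), 88.1 and 98.5 for prochloraz (28253 genes), 65.7 and 97.0 for propanil (27797 genes) and 68.7 and 95.5 for linuron (25710 genes). The number of arrays limits the precision.

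The alternatives fixed beforehand were quantile scaling, normexp background correction (offset 50) of the mean and local background signals, no intensity filter, every probe tested, the replicate letter or the slide as a block, the deposited value table, all arrays in one fit, leaving out each array in turn, the water or pooled controls as reference, and for lists the estimated correlation and the rotation test fry. Median scaling, normexp fitted without spots of high local background, and EE2 and flutamide in one fit with a slide block were added after the data were seen. Every slide held arrays of 3 or 4 groups, so the slide was taken as a block; scan day did not split any experiment.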

Results

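Zebrafish embryos were exposed to 7 compounds with known or suspected endocrine activity, and gene expression was compared between exposed and control embryos to describe the transcript changes that each compound brought. The compounds were EE2 (the synthetic estrogen ethinylestradiol), flutamide (a drug that blocks the androgen receptor), bisphenol A (a plastics monomer), methylparaben (a preservative), prochloraz (an imidazole fungicide), propanil and linuron (both herbicides). Each was given for 48 h at an EC10 and an EC20, concentrations set by an effect level that the labels do not describe further. Every sample was a pool of 24 whole embryos, measured on 1 single-colour oligonucleotide array. Each group held 4 samples, with replicate letters A to D. There were 92 deposited samples from 88 distinct arrays, because the 4 acetone solvent controls of EE2 were deposited again as those of flutamide. Bisphenol A, methylparaben and prochloraz were compared with water controls, EE2 and flutamide with solvent controls, and propanil and linuron had both. The arrays' 75th percentile of processed intensity ran from 362 to 802, and 63.8 to 82.4 percent of probes were well above background. Replicates of a group correlated at r = 0.972 to 0.994 across genes, which are not independent replicates. Values below are log2 changes with their standard error (SE) for n = 4 exposed against 4 control arrays, and adjusted p is from limma with Benjamini-Hochberg adjustment. Each gene named as a largest change had all 4 exposed arrays on one side of all 4 controls. Probe positions are on danRer5 (Zv7). A within-slide value is the difference between exposed and control arrays that shared a slide. For genes named as largest changes its direction followed from the separation of exposed from control arrays. A direction kept within slides is thus no further support for them. The p-values measure only the spread between these pooled samples, as nothing says that replicates came from separate parents or clutches.

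EE2 at 0.8 mg/l (EC20) raised tcap, a structural protein of the muscle sarcomere, by 2.17 ± 0.24 (adjusted p = 0.00473), with 1.57 at 0.65 mg/l (EC10, adjusted p = 0.0684). agt, which encodes the precursor of angiotensin, rose by 2.39 ± 0.33 at EC20 (adjusted p = 0.0309). fkbp5, a co-chaperone of steroid receptors and a known glucocorticoid target, fell by 1.42 ± 0.21 at EC20 (adjusted p = 0.0357) and showed -2.47 ± 0.21 at EC10 (adjusted p = 0.00109). ins, the insulin gene, fell by 1.31 ± 0.18 at EC20 (adjusted p = 0.03) and by 1.45 ± 0.18 at EC10 (adjusted p = 0.0143), and nfil3-6 was lower at EC10 by -1.07 ± 0.15 (adjusted p = 0.043). slc5a1, a sodium-coupled glucose transporter (chromosome 10, 13093013 to 13093072), was well above background on all 4 arrays of either concentration but on only 1 of 4 control arrays, so its rise has no firm size. The fit gave 3.93 ± 0.43 at EC20 (adjusted p = 0.00396) and 3.66 ± 0.43 at EC10 (adjusted p = 0.0135), while normexp gave 1.04 and 0.42, or 1.15 and 0.95 without spots of high local background, and ended the call in both forms (adjusted p over the alternatives 4.78e-13 to 0.996 at EC20 and 1.12e-11 to 0.637 at EC10). The estrogen-responsive yolk precursor vtg1 measured 1.22 ± 0.26 at EC20 (adjusted p = 0.421), brain aromatase cyp19a1b 0.19 and the estrogen receptor esr1 -0.09, none past the threshold. In all, 12 genes passed at EC20 (8 higher, 4 lower; 5 with names) and 8 at EC10 (4 higher, 4 lower; 4 with names), of 27115 tested. EC20 against EC10 gave 0 genes with limma, also in each other setting tried, with 110 at an unadjusted p under 0.05.

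Only 2 slides held both EE2 and control arrays, and with the slide as a block no named EE2 call held, while 2 genes passed at EC20 and 1 at EC10. With the slide block the EC20 changes were 2.25 for tcap (1.62 to 2.41 within slides), 2.18 for agt (2.53 to 2.66), -1.17 for fkbp5 (-1.18 to -1.17) and -1.19 for ins (-1.33 to -1.23). slc5a1 was higher on both slides, without a firm size. At EC10, fkbp5 was -2.22 with the block (-2.41 to -2.02), ins -1.33 (-1.54 to -0.93) and nfil3-6 -1.12 (-1.28 to -0.97). With EE2 and flutamide in one fit and a slide block, 26 genes passed at EC20 and 13 at EC10. That fit kept the calls of slc5a1, tcap (2.14), agt (2.23), fkbp5 (-1.33, and -2.39 at EC10), ins (-1.22) and nfil3-6 (-1.05 at EC10). The EC20 calls of agt and fkbp5 also ended with the replicate block, where letters A to D paired the EE2 samples (adjusted p = 0.109 and 0.0981; over the alternatives 3.41e-07 to 0.996 for agt and 0.0171 to 0.506 for fkbp5). The EC20 calls of agt, fkbp5 and ins and the EC10 call of nfil3-6 also ended with normexp, with no filter and with the series values, those of fkbp5 and ins with median scaling too, and ins at EC10 with normexp, the series values and median scaling. Normexp fitted without spots of high local background kept these calls of agt, fkbp5, ins and nfil3-6. tcap lost its call only with the slide block. Without single arrays, fkbp5 kept its EC20 call only when EC10 A was left out (adjusted p up to 0.190 otherwise), agt only without EC10 A, EC10 B or EC20 B (up to 0.147), and ins only without EC10 A, EC10 C or EC20 D (up to 0.147). At EC10, slc5a1 lost its call without solvent control B or any of EC10 A to D (up to 0.0699), ins without solvent control A, B or D or EC10 B, C or D (up to 0.0891), and nfil3-6 without any array but EC20 D (up to 0.250). The EC20 count became 6, 6, 7 and 7 without solvent controls A, B, C and D, 7 and 6 without EC10 B and D, and 6, 7 and 6 without EC20 A, B and C. The EC10 count became 2, 2 and 4 without solvent controls A, B and D, and 2, 1, 3 and 1 without EC10 A, B, C and D. The split of higher and lower calls at EC20 was 8 and 1 with median scaling, 6 and 0 with the deposited series values, 2 and 0 with normexp, and 5 and 4 with normexp fitted without spots of high local background. At EC10 it was 3 and 1 with the series values, 0 and 1 with normexp, and 1 and 5 without those spots.

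With camera 5 gene lists passed with EE2 at EC20 (3 higher, 2 lower) and 10 at EC10 (2 higher, 8 lower), 0 of them with an estimated correlation. With the slide block 3 of these 5 and 7 of these 10 stayed past the threshold. At EC20 the 27 measured cholesterol synthesis genes had a median of 0.21 with 0 called, also when adjusted over the list alone (limma camera, adjusted p = 2.27e-05; adjusted p = 0.113 with an estimated correlation), 0.22 with the slide block and 0.09 to 0.28 within slides. The 40 genes of the unfolded protein and integrated stress response had a median of 0.16 with 0 called, 2 when adjusted over the list alone (adjusted p = 1.73e-06; adjusted p = 0.3 with an estimated correlation), 0.17 with the block and 0.11 to 0.13 within slides. The smallest p at EC10 was that of the 77 ribosomal protein genes, with a median of -0.09 and 0 called, also when adjusted over the list alone (adjusted p = 4.76e-07; adjusted p = 0.616 with an estimated correlation), -0.09 with the block and -0.17 to -0.01 within slides. The 35 liver genes followed with a median of -0.23 and 0 called, also when adjusted over the list alone (adjusted p = 5.82e-05; adjusted p = 0.573 with an estimated correlation), -0.30 with the block and -0.77 to -0.11 within slides. The 24 glucocorticoid response genes had at EC10 a median of -0.11 with 1 lower, 2 lower when adjusted over the list alone (adjusted p = 0.00134; adjusted p = 0.522 with an estimated correlation). That list's shift was 0.06 to 0.17 within slides, against its direction, and it was not past the threshold with the slide block.

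Flutamide, compared with the same 4 control arrays, left few single genes past the threshold. At 1.4 mg/l (EC20) 2 genes rose, of 27247 tested, and 1 of them had a name: irg1l, an immune-responsive gene, by 0.93 ± 0.11 (adjusted p = 0.0348; 0.60 at EC10, adjusted p = 0.37). At 1.2 mg/l (EC10) 3 genes passed, 2 higher and 1 lower. The lower was ins, by -1.61 ± 0.14 (adjusted p = 0.00114; within slides -1.75 to -1.66), chosen after its values were seen. No single array ended that call, but the slide block did (-1.65, adjusted p = 0.155; 0.0197 with the replicate block). Between the concentrations ins was higher at EC20 than at EC10 by 1.90 ± 0.14 (adjusted p = 0.000249; 1.62 to 2.00 within slides), 1 of 3 genes past the threshold (1 higher, 2 lower). vtg1 measured 1.57 ± 0.29 at EC10 (adjusted p = 0.37) and -0.18 at EC20.

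The irg1l call ended without any of the 12 arrays (adjusted p up to 0.232) and with the slide block (0.91; 0.77 to 1.11 within slides), and the EC20 count was then 1 without solvent control B and 0 without each of the other arrays or with the block. With the block the EC10 count was 0 and EC20 against EC10 gave 3. Of the other settings with no array left out, only every probe tested and EE2 and flutamide in one fit with a slide block kept the irg1l call. EC20 against EC10 gave 5 genes without EC10 D and 5 without EC20 D, and the replicate block gave 4. The EC20 against EC10 split was 2 and 2 with quantile scaling or the series values, and 1 and 0 with normexp fitted without spots of high local background, which gave 0 and 1 at EC10. With camera 7 gene lists passed with flutamide at EC20 and 9 at EC10, of which 2 and 6 stayed past the threshold with the slide block. At EC20 the 36 genes of the macrophage, neutrophil and inflammation list had a median of 0.16 with 1 called, 3 when adjusted over the list alone (limma camera, adjusted p = 3.31e-07; adjusted p = 0.278 with an estimated correlation), 0.15 with the slide block and 0.21 to 0.23 within slides. Ribosomal protein genes (77 measured) had at EC10 a median of -0.18 with 0 called, also when adjusted over the list alone (adjusted p = 2.02e-10; adjusted p = 0.522 with an estimated correlation), -0.14 with the slide block and -0.28 to -0.02 within slides.

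Bisphenol A at 8.5 mg/l (EC20) raised gstp1.1, a pi-class glutathione transferase (chromosome 14, 55733892 to 55733951), by 3.01 ± 0.19 (adjusted p = 2.85e-05; slide block 2.99, within 3 slides 2.84 to 3.29), and by 3.33 at 8 mg/l (EC10). agt (chromosome 13, 25101659 to 25101718) rose by 3.30 ± 0.33 (adjusted p = 0.000843; 3.27, 2.85 to 3.43). Further rises were in tpmt.2 (2.21 ± 0.26), a thiopurine methyltransferase, ugt1a1 (1.53 ± 0.20), a glucuronosyltransferase, gstp1.2 (1.32 ± 0.14), gsr (0.95 ± 0.13), glutathione reductase, ethe1 (1.51 ± 0.08), uox (1.48 ± 0.15), the enzyme urate oxidase, and hpdb (1.38 ± 0.19), with adjusted p from 2.18e-05 for ethe1 to 0.0068 for hpdb. cyp19a1b rose by 0.68 ± 0.08 (adjusted p = 0.00335; slide block 0.67, within slides 0.47 to 0.84), while a further probe of that gene had the opposite sign. The glucocorticoid target fkbp5 (chromosome 6, 27969282 to 27969341) fell by 3.43 ± 0.38 (adjusted p = 0.00157; slide block -3.42, within slides -3.72 to -3.06), with -3.37 at EC10. Also lower were smpx by -1.32 ± 0.15 and apobec2b, measured on 3 of 4 EC20 arrays, by -1.16 ± 0.14 (adjusted p = 0.00244 and 0.00256). vtg1 measured 0.52 ± 0.22 (adjusted p = 0.302), esr1 0.02 and cyp1a -0.04.

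The Nrf2 antioxidant list had 30 measured genes, of which 6 were called higher at EC20, 16 higher and 1 lower when adjusted over the list alone. Its median was 0.28 (limma camera, adjusted p = 2.58e-08; adjusted p = 0.287 with an estimated correlation), 0.28 with the slide block and 0.10 to 0.28 within slides. In the unfolded protein and integrated stress response 2 of 40 genes were higher, 7 when adjusted over the list alone, with a median of 0.14 (adjusted p = 1.34e-05; adjusted p = 0.241 with an estimated correlation), 0.14 with the slide block and 0.12 to 0.18 within slides; dnajc3a, a chaperone of the endoplasmic reticulum, rose by 0.49 ± 0.08 (adjusted p = 0.00982). Of 35 liver genes 4 rose and 1 fell, also when adjusted over the list alone, with a median of 0.25 (adjusted p = 0.000526; adjusted p = 0.647 with an estimated correlation), 0.20 with the block and -0.07 to 0.49 within slides. In all 288 genes passed at EC20 (156 higher, 132 lower) and 357 at EC10 (199 higher, 158 lower) of 26800 tested, 59 and 63 of them by over 2-fold. EC20 against EC10 gave 0 with limma and in each other full-sample setting, with 1395 at an unadjusted p under 0.05, and 1 when EC20 D was left out. With the slide block 199 passed at EC20 and 247 at EC10. All 26 named genes called at EC20 kept their direction within each of the 3 slides, which for the largest changes followed from their choice. Normexp kept 18 of these calls, or 20 without spots of high local background. Median scaling turned the split to 111 higher and 152 lower at EC20 and 139 and 177 at EC10, and normexp gave 87 and 43 at EC20, or 128 and 58 without spots of high local background. The EC20 count became 168 and 165 without water controls B and D, 191 without EC10 B, and 155 and 158 without EC20 B and C. The EC10 count became 175 and 161 without water controls B and D, and 137, 132, 156 and 232 without EC10 A, B, C and D.

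**Figure D1:**
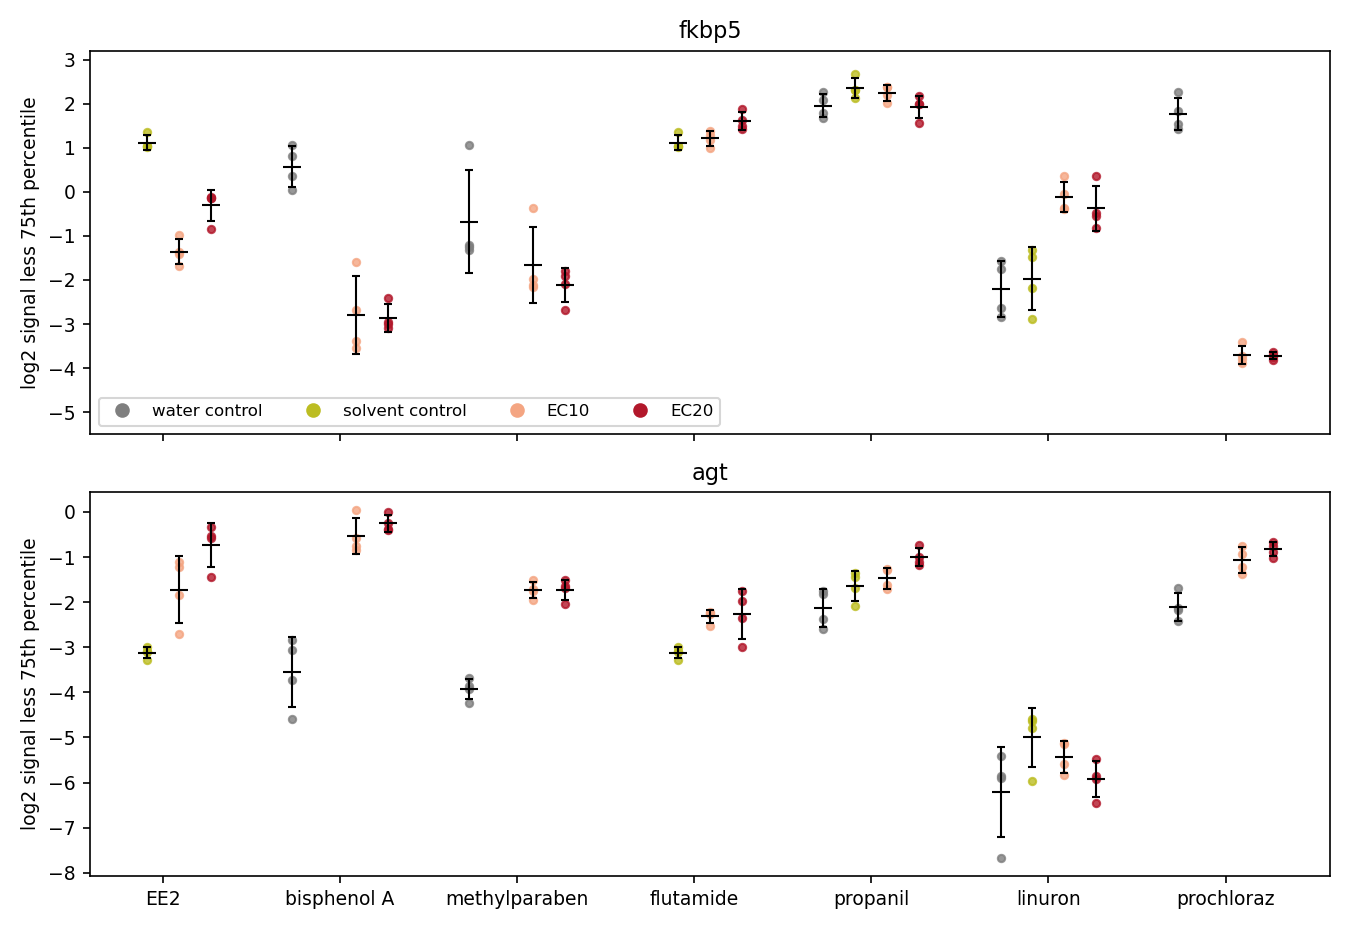
Log2 level of fkbp5 and agt relative to each array's 75th percentile in every sample, with bars for group means and SD, by compound and group. With prochloraz fkbp5 at EC20 differed from the water control by -5.49, and with bisphenol A agt differed by 3.30.

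Methylparaben changed far more genes. At 24.4 mg/l (EC20), cyp4v2a, a cytochrome P450 (chromosome 1, 13744087 to 13744146), fell by 3.61 ± 0.18 (adjusted p = 9.55e-07; slide block -3.61, within 3 slides -3.99 to -3.45). g6pc1a.1, a catalytic subunit of glucose-6-phosphatase (chromosome 12, 4021784 to 4021843), measured on 3 of 4 EC20 arrays, fell by 2.99 ± 0.12 (adjusted p = 3.41e-07; -3.01, -3.23 to -2.85). The yolk precursor vtg1 (chromosome 22, 23098713 to 23098772) rose by 1.94 ± 0.16 (adjusted p = 3.31e-05; 2.01, 1.79 to 2.09) and vtg5 was at least 2.33-fold higher, while cyp19a1b measured 0.20 and esr1 -0.27. irf7, an interferon regulatory factor, rose by 1.80 ± 0.11 (adjusted p = 4.34e-06; 1.81, 1.77 to 1.88) and the ubiquitin-like isg15 by 2.81 ± 0.39 (adjusted p = 0.000928; 2.59, 1.44 to 3.21). agt rose by 2.2 ± 0.14 (adjusted p = 6.33e-06; 2.16, 2.00 to 2.27). At least 4.71-fold lower was col10a1a, a collagen, and at least 3.53-fold lower gvin1l2, which had the opposite sign with normexp.

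Of 34 liver genes measured with methylparaben at EC20, 16 fell and 1 rose (18 and 1 when adjusted over the list alone), with a median of -0.39 (limma camera, adjusted p = 1.23e-08; adjusted p = 0.287 with an estimated correlation), -0.35 with the slide block and -0.43 to -0.22 within slides. Examples were apoa4a, an apolipoprotein (-1.65 ± 0.16), vtna, vitronectin (-1.43 ± 0.12), and fgb, the fibrinogen beta chain (-0.89 ± 0.08), with adjusted p = 9.27e-05, 2.79e-05 and 3.48e-05. Of 26 cholesterol synthesis genes 8 rose and 3 fell (11 and 4 when adjusted over the list alone), with a median of 0.23 (adjusted p = 0.00998; adjusted p = 0.347 with an estimated correlation), 0.18 with the slide block and 0.06 to 0.35 within slides. Among them cyp51, lanosterol demethylase, rose by 1.27 ± 0.22 (adjusted p = 0.00321; 0.93 to 1.43 within slides). Of 42 xenobiotic CYP, UGT, SULT and transporter genes 14 fell and 2 rose (15 and 2 when adjusted over the list alone), with a median of -0.12 (adjusted p = 0.00308; adjusted p = 0.488 with an estimated correlation), -0.14 with the slide block and -0.36 to -0.05 within slides. The sulfotransferases sult2st2 (-0.95), sult1st4 (-0.82) and sult1st6 (-1.09) were among those lower. Heat shock genes had a median of -0.12 with 7 of 21 lower, also when adjusted over the list alone (adjusted p = 0.00247; adjusted p = 0.241 with an estimated correlation), -0.13 with the slide block and -0.25 to -0.19 within slides, dnajb1a at -0.57 among them.

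In all 3590 genes passed with methylparaben at EC20 (1780 higher, 1810 lower) and 2186 at 19.8 mg/l, the EC10 (1024 higher, 1162 lower), of 25105 tested. Over 2-fold changes numbered 342 and 250. EC20 against EC10 gave 1 gene, agxt2 (-0.70 ± 0.08, adjusted p = 0.0454), chosen after its values were seen, which lost its call without any of the 12 arrays and with the slide block (-0.73; -0.80 to -0.68 within slides), leaving 0. With the slide block 3001 passed at EC20 and 1810 at EC10. All 32 named genes called at EC20 kept their direction within each slide, which for the largest changes followed from their choice. Normexp kept 16 of these calls, but 31 without spots of high local background. The EC20 split was 1282 and 2009 with median scaling and 164 and 277 with normexp, which gave 64 and 138 at EC10. The EC20 count became 2071 and 2091 without water controls A and D, and 2374, 2214 and 2209 without EC20 A, B and C. The EC10 count became 1225 and 1283 without water controls A and D, and 1294 and 1249 without EC10 A and D.

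Prochloraz lowered fkbp5 more than any other gene named here, by -5.49 ± 0.16 at 2 mg/l (EC20, adjusted p = 1.42e-08; slide block -5.42, within 3 slides -5.86 to -5.15) and -5.46 at 1.7 mg/l (EC10). klf9, another transcription target of the glucocorticoid receptor, measured on 3 of 4 EC20 arrays, fell by 2.21 ± 0.19 (adjusted p = 0.000154; -2.31, -2.64 to -1.94). The clock repressor nr1d2a fell by 1.97 ± 0.12 (adjusted p = 7.69e-06; -1.96, -2.03 to -1.84), cyp24a1, which inactivates vitamin D, by 1.61 ± 0.18 (adjusted p = 0.0011), klf3 by 1.51 ± 0.07 (adjusted p = 9.89e-07) and tcap by 1.44 ± 0.18 (adjusted p = 0.00226). Rises among the named genes were smaller: cyp1a, the classical target of the aryl hydrocarbon receptor (chromosome 18, 1584808 to 1584867), by 1.30 ± 0.18 (adjusted p = 0.00542; 1.21, 0.99 to 1.34), agt by 1.28 ± 0.17 (adjusted p = 0.00317; 1.25, 1.04 to 1.56) and pmt by 1.20 ± 0.10 (adjusted p = 0.000129). cyp51, the enzyme that azole fungicides are made to inhibit in fungi, measured 0.08, vtg1 0.41 and cyp19a1b -0.18.

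Of 15 aryl hydrocarbon receptor targets 2 rose with prochloraz at EC20, 5 higher and 1 lower when adjusted over the list alone. Their median was 0.16 (limma camera, adjusted p = 0.00273; adjusted p = 0.467 with an estimated correlation), 0.17 with the slide block and 0.11 to 0.29 within slides. In the unfolded protein and integrated stress response 4 of 40 rose (8 higher and 2 lower when adjusted over the list alone), with a median of 0.13 (adjusted p = 0.000738; adjusted p = 0.287 with an estimated correlation), 0.13 with the slide block and 0.10 to 0.16 within slides; sesn2 (0.70 ± 0.06) and psat1 (0.65), a serine synthesis enzyme, were among the named rises. At EC20 camera did not call the 24 glucocorticoid response genes lower (5 lower and 1 higher, 6 and 4 when adjusted over the list alone; median -0.04, adjusted p = 0.083; adjusted p = 0.603 with an estimated correlation), with -0.05 for the slide block and -0.03 to 0.07 within slides. At EC10 5 of these 24 were lower (6 lower and 3 higher when adjusted over the list alone), with a median of -0.01 and a mean of -0.40 (adjusted p = 0.00359; adjusted p = 0.467 with an estimated correlation). That median was -0.03 with the slide block and -0.01 to 0.03 within slides. In all 211 genes passed at EC20 (87 higher, 124 lower) and 116 at EC10 (27 higher, 89 lower) of 28316 tested, 40 and 33 by over 2-fold. EC20 against EC10 gave 0 with limma and in each other full-sample setting, with 1151 at an unadjusted p under 0.05, and 1 without EC20 B. With the slide block 175 passed at EC20 and 72 at EC10. All 25 named genes called at EC20 kept their direction within each slide, which for the largest changes followed from their choice. Both forms of normexp gave 150 higher and 125 lower at EC20. The EC20 count became 134, 132 and 324 without water controls B, C and D, and 125 without EC20 C. The EC10 count became 67 and 65 without water controls A and C, and 64, 67 and 65 without EC10 B, C and D, and the cyp1a call at EC10 ended without water control C, EC10 B or EC10 D (adjusted p up to 0.0615).

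Propanil changed genes at its EC20, and none passed at its EC10. At 1.1 mg/l, fads2, a desaturase of polyunsaturated fatty acid synthesis (chromosome 25, 875824 to 875883), rose by 1.75 ± 0.12 (adjusted p = 2.95e-05; slide block 1.75, within 4 slides 1.26 to 2.11), with -0.14 at 0.8 mg/l (EC10). cyp3a65, a xenobiotic-metabolising P450, rose by 1.43 ± 0.20 (adjusted p = 0.00309; 1.13 to 1.99 within slides), with 0.06 at EC10. kcnj1a.2, a potassium channel gene, rose by 1.28 ± 0.15 (adjusted p = 0.00124; 1.11 to 1.41), the clock gene per2 by 1.02 ± 0.13 (adjusted p = 0.00185; 0.82 to 1.45) and ugt1a1 by 0.86 ± 0.09 (adjusted p = 0.000437). The galectin-binding lgals3bp.1 fell by 1.07 ± 0.11 (adjusted p = 0.000437; -1.40 to -0.79) and lgals3bp.3 by 0.94 ± 0.11 (adjusted p = 0.00132). ms4a17a.6, measured on only 1 of 4 EC20 arrays, fell by 1.42 ± 0.19 (adjusted p = 0.0028; -1.79 to -0.85), with the opposite sign under normexp. vtg1 measured 0.96 (adjusted p = 0.201).

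Of 27 cholesterol synthesis genes 5 rose with propanil, 12 when adjusted over the list alone. Their median was 0.22 (limma camera, adjusted p = 1.58e-14; adjusted p = 0.117 with an estimated correlation), 0.22 with the slide block and 0.13 to 0.40 within slides. Examples were hmgcs1, which makes the substrate of the pathway's committed step (0.63 ± 0.08, adjusted p = 0.0028; 0.35 to 0.88 within slides), and lss, lanosterol synthase (1.08 ± 0.20, adjusted p = 0.0213), whose call ended without solvent control B, C or D or EC20 A, C or D (adjusted p up to 0.0841). In the lipid and fatty acid list 4 of 43 rose and 1 fell (13 and 2 when adjusted over the list alone), with a median of 0.09 (adjusted p = 2.94e-07; adjusted p = 0.113 with an estimated correlation), 0.09 with the slide block and 0.02 to 0.17 within slides, hadhaa of fatty acid oxidation at 0.71 ± 0.09 among them. The unfolded protein and integrated stress response had 4 of 40 higher, 5 when adjusted over the list alone, with a median of 0.09 (adjusted p = 1.37e-06; adjusted p = 0.287 with an estimated correlation), 0.09 with the slide block and 0.01 to 0.14 within slides, but its test direction turned with normexp (median 0.0277), asparagine synthetase asns at 0.55 ± 0.08 among them. In all 143 genes passed at EC20 (100 higher, 43 lower; 20 by over 2-fold) of 27933 tested. At EC10 limma gave 0, with 692 at an unadjusted p under 0.05, and each other setting 0 but the water reference with 1. EC20 against EC10, the test of the difference itself, gave 120 genes (95 higher, 25 lower).

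Against water controls the propanil EC20 count was 502, against both controls pooled 385, and solvent against water gave 0 (limma, 2064 at an unadjusted p under 0.05), with 1 from the series values. With the slide block 166 passed. All 25 named genes called kept their direction within each of the 4 slides, which for the largest changes followed from their choice. Normexp kept 7 of these 25 calls (16 lost, 2 turned), but 23 without spots of high local background. All arrays in one fit kept 13, median scaling 20 and the slide block 24. Normexp gave 16 higher and 1 lower at EC20 and 7 and 0 between the concentrations. The EC20 count became 80, 88 and 90 without solvent controls B, C and D, and 71 and 89 without EC20 A and D. The EC20 against EC10 count became 76 and 65 without EC10 B and D, and 51 without EC20 A.

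Linuron lowered contractile genes at 1.3 mg/l (EC20). casq2, the calcium-binding protein of the heart muscle's calcium store (chromosome 9, 27072603 to 27072662), fell by 3.62 ± 0.90 (adjusted p = 0.0116; slide block -3.62, within 4 slides -4.88 to -1.30). The sarcomeric actin actc1b (chromosome 17, 39398785 to 39399615) fell by 3.40 ± 0.71 (adjusted p = 0.00553; -4.34 to -1.52), the sarcomere protein myoz1b by 3.14 ± 0.59 (adjusted p = 0.00379; -4.04 to -1.67) and the calcium pump atp2a1l by 1.57 ± 0.25 (adjusted p = 0.00291; -2.13 to -1.06). The lens gene lgsn fell by 1.16 ± 0.18 (adjusted p = 0.00286; -1.63 to -0.50). Among the largest rises were ankar (3.93 ± 0.69, adjusted p = 0.00355; 3.21 to 4.34) and nr4a3, an immediate-early nuclear receptor (2.80 ± 0.55, adjusted p = 0.00429; 1.10 to 4.44). fkbp5 rose by 1.59 ± 0.36 (adjusted p = 0.00811; 0.78 to 2.07), the heat shock gene hsp70l by 0.66 ± 0.14 (adjusted p = 0.00623; 0.28 to 1.36) and cyp19a1b by 0.69 (adjusted p = 0.0207), whose call ended without solvent control C, EC20 B or EC20 D (adjusted p up to 0.0633). The rise of fzd3b, 2.92 ± 0.60, was opposed by its other probe.

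Tissue lists were lower with linuron at EC20 than in solvent controls. Of 20 heart muscle genes 13 fell, 17 when adjusted over the list alone, with a median of -0.90 (limma camera, adjusted p = 3.29e-08; adjusted p = 0.477 with an estimated correlation) and -1.66 to -0.17 within slides. Of 33 fast skeletal muscle genes 21 fell and 1 rose (21 and 2 when adjusted over the list alone), with a median of -0.60 (adjusted p = 6e-08; adjusted p = 0.488 with an estimated correlation) and -0.96 to -0.38 within slides. Of 36 lens genes 22 fell and 2 rose (24 and 2 when adjusted over the list alone), with a median of -0.46 (adjusted p = 7.84e-11; adjusted p = 0.347 with an estimated correlation) and -0.73 to -0.37 within slides. The 33 liver genes had 15 lower and 3 higher (19 and 4 when adjusted over the list alone) and a median of -0.99 (adjusted p = 3.51e-05; adjusted p = 0.615 with an estimated correlation), but -2.12 to 0.46 within slides. Of 65 mitochondrial respiration genes 21 fell, 23 when adjusted over the list alone, with a median of -0.29 (adjusted p = 3.34e-09; adjusted p = 0.616 with an estimated correlation) and -0.69 to 0.04 within slides. Ribosomal protein genes went the other way, 22 of 77 higher and 1 lower (27 and 1 when adjusted over the list alone), with a median of 0.25 (adjusted p = 0.000262; adjusted p = 0.707 with an estimated correlation) and 0.05 to 0.48 within slides, which turned to -0.09 with quantile scaling. The exposed linuron arrays were also dimmer, with a 75th percentile of 362 to 444 at EC20 and 408 to 490 at EC10 against 486 to 597 in solvent and 537 to 605 in water controls. Slides matched the replicate letters here, so each slide held all groups and the slide-block medians equalled those without it. Against water controls the list medians were -0.41 for fast skeletal muscle (8 lower, 1 higher), -0.31 for heart muscle (4 lower), -0.53 for lens (21 lower, 2 higher) and 0.0332 for liver (0 lower, 1 higher), so the liver fall was seen only against solvent controls and the muscle falls were smaller. With that reference mitochondrial respiration had -0.06 (5 lower, 1 higher) and ribosomal proteins 0.33 (34 higher, 1 lower). With that reference 5152 genes passed and 25 of the 33 named EC20 calls held.

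**Figure D2:**
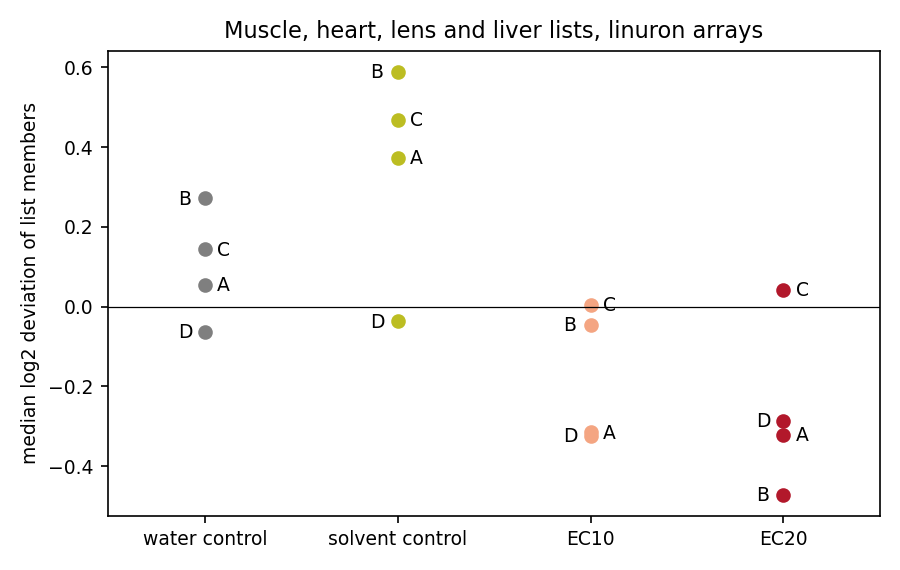
Tissue list level of each linuron array, the median over members of the muscle, heart, lens and liver lists of the log2 deviation from the 16-array mean, by group, with replicate letters. The solvent controls lay from -0.04 (D) to 0.59 (B) and the EC20 arrays from -0.47 (B) to 0.04 (C). Water controls lay from -0.06 (D) to 0.27 (B), below solvent controls A to C, and EC20 C lay within their range.

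In all 6726 genes passed with linuron at EC20 (4188 higher, 2538 lower) and 1800 at 1.2 mg/l, the EC10 (867 higher, 933 lower), of 25739 tested, with over 2-fold changes numbering 1698 and 589. At EC10 the heart muscle list had a median of -1.03 with 12 of 20 lower, 16 when adjusted over the list alone (limma camera, adjusted p = 1.4e-10; adjusted p = 0.432 with an estimated correlation) and -1.51 to -0.43 within slides. The EC10 count was 1, 9, 14 and 6592 without solvent controls A, B, C and D, 1, 31, 3270 and 1 without EC10 A, B, C and D, 1002, 18 and 780 without water controls A, C and D, and 2932 without EC20 C. All 21 named genes called at EC10 lost the call when some single array was left out, and the count was 2 against water controls, 560 against pooled controls and 39 with no intensity filter. The EC20 count was 3450 and 3382 without EC20 A and B. EC20 against EC10 gave 0 genes with limma (1660 at an unadjusted p under 0.05; 126 with all arrays in one fit), 5 without EC20 C and 1 without EC20 D. Solvent against water also gave 0 (3100 at an unadjusted p under 0.05; 1123 with all arrays in one fit), 5 without water control B and 1184 without solvent control D. With the slide block 8757 passed at EC20 and 4914 at EC10, and 30 of 33 named genes called at EC20 kept their direction within each of the 4 slides. Normexp kept 21 of these calls, or 29 without spots of high local background. Normexp gave 749 at EC20 and 0 higher and 3 lower at EC10. Without spots of high local background it gave 10195 higher and 2410 lower at EC20 and 3624 and 1574 at EC10.

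**Figure D3:**
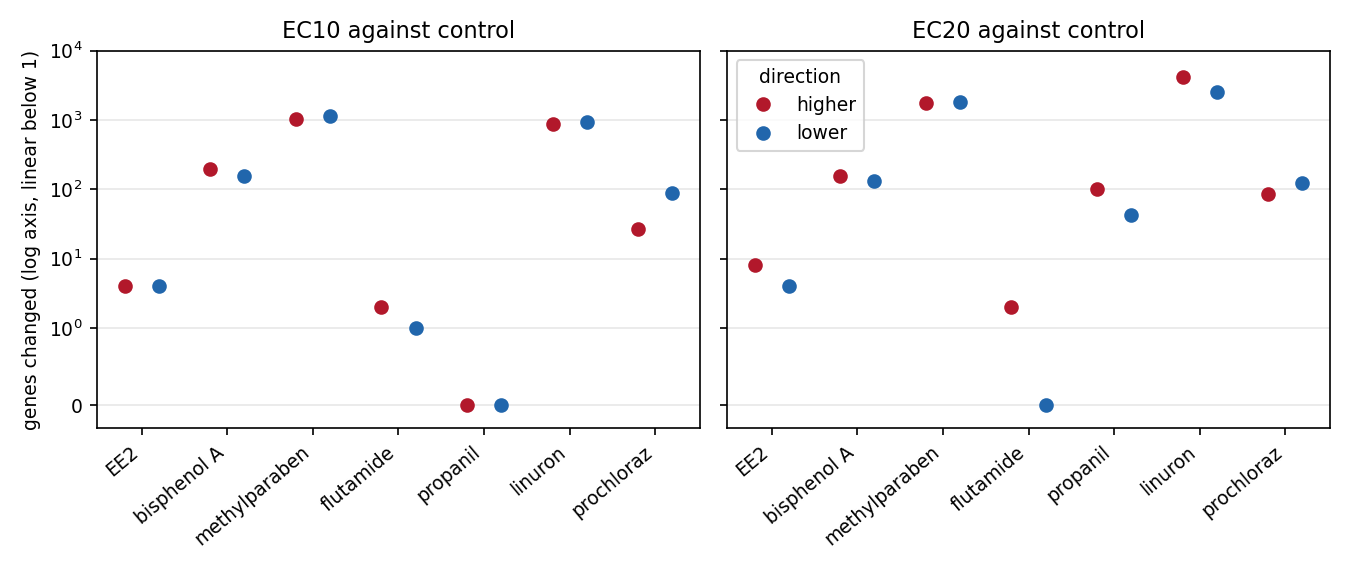
Number of genes past the threshold (limma, adjusted p under 0.05) higher and lower than control at EC10 and EC20 of each compound. The largest total was 6726 with linuron at EC20 and the smallest 0 with propanil at EC10.

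Propanil and linuron both carry a 3,4-dichlorophenyl ring on a nitrogen, in an amide and in a urea, and propanil and flutamide are both acyl anilides, so their changes were compared at matched effect levels. The concentrations differed: 1.1, 1.3 and 1.4 mg/l at EC20 for propanil, linuron and flutamide. Propanil and linuron differed in fads2 by 1.94 ± 0.20 (95 percent interval 1.53 to 2.35, adjusted p = 8.81e-06; propanil 1.75, linuron -0.19). The difference was 0.97 for hmgcs1 (0.62 to 1.31, adjusted p = 0.00125), 1.31 for cyp3a65 (0.63 to 2.00, adjusted p = 0.00938) and -2.02 for fkbp5 (-2.88 to -1.17, adjusted p = 0.00292; propanil -0.43, linuron 1.59). The fkbp5 levels of the solvent controls lay far apart, 2.13 to 2.67 with propanil and -2.89 to -1.33 with linuron. The muscle genes casq2 and actc1b differed by 3.73 ± 0.96 (adjusted p = 0.0101) and 3.5 ± 0.76 (adjusted p = 0.00382). Differences that did not pass were 0.15 for nfil3-6 (-0.38 to 0.68, adjusted p = 0.721), -0.20 for marco (-0.75 to 0.34, adjusted p = 0.626) and -0.48 for cyp1a (-1.01 to 0.04, adjusted p = 0.189). Propanil and flutamide differed in fads2 by 1.87 ± 0.20 (1.45 to 2.29, adjusted p = 8.38e-05) and in kcnj1a.2 by 1.35 (0.87 to 1.82, adjusted p = 0.0127), the latter call ending without propanil solvent control A (adjusted p = 0.0513). Of the 7 named calls of this pair at EC20 normexp kept 0 (4 lost, 3 turned). Normexp without spots of high local background and all arrays in one fit kept 4 each. Of the 10 named for propanil and linuron normexp kept 3, or 10 without those spots. Not past were agt at -0.21 (-0.84 to 0.43) and marco at 0.08 (-0.32 to 0.49). Some of the genes given with intervals were chosen after their values were seen.

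Between propanil and linuron 4837 genes differed at EC20 (1971 higher, 2866 lower) and 511 at EC10 (306 higher, 205 lower), of 28572 tested. Between propanil and flutamide 14 differed at EC20 (6 higher, 8 lower) and 1 at EC10, ins (1.65 ± 0.15, adjusted p = 2.19e-06; slide block 1.69), chosen after its values were seen. With the slide block the counts were 6965 and 2510 for linuron and 9 and 1 for flutamide. The propanil and linuron split was 2663 and 2531 at EC20 with quantile scaling, and at EC10 60 and 21 with median scaling; normexp fitted without spots of high local background gave 1951 and 9190, and 480 and 646. Against flutamide the EC20 split was 2 and 8 with median scaling, and the EC10 split 1 and 2 with the series values. At EC20 the linuron count became 7398 without linuron solvent control D, 3165 without linuron EC20 B and 7269 without linuron EC20 C, and the flutamide count 22 without flutamide solvent control D. At EC10 the flutamide count was 2 without flutamide EC10 D. The EC10 linuron count became 209, 208, 203 and 235 without propanil water controls A to D in turn, 31, 7, 6 and 63 without its solvent controls, 8, 7, 41 and 25 without its EC10 arrays, and 210, 204, 201 and 228 without its EC20 arrays. It became 218 and 278 without linuron water controls C and D, 6, 13, 97 and 4206 without linuron solvent controls A to D, 7, 2018 and 5 without linuron EC10 A, C and D, and 1522 without linuron EC20 C.

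Across compounds at EC20, 921 genes were called the same way in at least 2 compounds, 325 higher and 596 lower, and 2 and 2 in at least 4 compounds. agt was higher with EE2 (2.39), bisphenol A (3.30), methylparaben (2.2) and prochloraz (1.28). marco, a macrophage scavenger receptor, was higher with bisphenol A (0.45), methylparaben (1.10), propanil (0.65) and linuron (0.85). With 1 array left out at a time, the marco call with bisphenol A held only without water control C or EC20 C (adjusted p up to 0.108 otherwise), that with propanil only without water control D, EC10 A, EC10 D or EC20 C (up to 0.131), and that with linuron ended without EC20 B (0.0522). nfil3-6, a clock-related transcription factor, was lower with methylparaben (-0.91), propanil (-0.73), linuron (-0.88) and prochloraz (-0.93), the linuron call ending without EC20 B (adjusted p = 0.0564). Most single omissions ended the EE2 calls of agt and fkbp5. fkbp5 was lower with EE2 (-1.42), bisphenol A (-3.43) and prochloraz (-5.49), and higher with linuron (1.59). With methylparaben it did not pass (-1.44 ± 0.54, adjusted p = 0.103), with all EC20 arrays below all controls. Its control levels differed between experiments, from -2.89 to -1.33 in linuron solvent controls against 1.42 to 2.26 in prochloraz water controls. The linuron EC20 arrays (-0.82 to 0.35) still lay below the latter, and why the controls differed was not tested. Bisphenol A and methylparaben shared 50 genes higher and 56 lower, where independent lists would share 10.5 and 9.35. Most of the 921 came from methylparaben and linuron, which shared 201 higher (274 for independent lists) and 481 lower (183), with 436 opposite (459). Bisphenol A and linuron shared 6 higher (23.4) and 19 lower (12.9), with 55 opposite (35.2). The changes of EE2 and flutamide, taken against the same control arrays, correlated at r = 0.438 across genes, where simulated unchanged groups against shared controls gave 0.50, and their covariance was 0.0240 against 0.0509. With the controls split between the compounds r ran from -0.462 to -0.00764. Each split gave the compounds controls of different letters, which sets their changes apart where letters move together. These values therefore do not decide whether the 2 compounds share changes.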

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

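In this part the tests of the other fkbp5 probe, of further glucocorticoid genes, of an exchange of a pair of linuron arrays, of slide differences in the liver list, of delayed development, of splits that part every slide and of letters against slides in EE2 were chosen only after the result was seen; the others were planned. An array is given as standing apart where its gap to the nearest replicate exceeded Dixon's 95 percent limit as a share of the group's range. This held in 54 of 741 groups tested, where chance gives 37.05, about 1 in 20.

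fkbp5 was lower with EE2, bisphenol A and prochloraz. The values argue against a fault of the probe, since the other fkbp5 probe showed -5.97 with prochloraz at EC20. The highest within-slide change over the 3 compounds at EC20 was -1.17. As every EC20 array lay below every control of its compound, a negative sign was certain, so the sign says nothing about slide differences. With bisphenol A and prochloraz the sizes within slides, given above, were close to the full changes, which argues against slide differences there. For EE2 the slide block ended the call. Of 23 other measured glucocorticoid response genes 4 were lower with prochloraz at EC20 (pfkfb4b -1.31, klf9 -2.21, g6pc1a.2 -1.12, hsd11b2 -0.49), against 120 of the genes outside these 23, fkbp5 among them, of 28316 tested (one-sided Fisher's exact test, p = 2.91e-06), while igfbp1a was higher (0.55), and tsc22d3 (-0.12), per1a (-0.21), sgk1 (0.08) and dusp1 (-0.11) did not pass. As camera did not call this list lower at EC20, lower glucocorticoid receptor signalling with prochloraz is only a candidate explanation, found and tested on the same data, and the other compounds' changes stay open.

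Muscle, heart, lens and liver genes were lower with linuron at EC20 than in solvent controls, while against water controls the liver median was 0.0332. Dimmer arrays as the whole cause are argued against by brightness-matched genes, as the median of the 148 members (-0.67) lay -0.78 from the matched median (0.11, 1000 draws). Each slide held an array of every group, so differences between slides cancel in these changes, which argues against them as the cause. The highest within-slide median was -0.27 for the 5 lists together and below 0 for each of muscle, heart and lens. For liver alone the medians ran from -2.12 to 0.46 over 4 slides, so its fall was not seen on every slide. An exchange of the labels of solvent control D (-0.04) and EC20 C (0.04) stays open. Against it, 0 of the 2 arrays lay in the tissue list range of the other group's 3 other arrays. Both also had the brightness of their own label (75th percentile 362 to 444 at EC20, 486 to 597 in solvent controls). But the grouping with these labels exchanged called 6779 genes against 6726. Delayed development stays open as well: against solvent controls the rise it would need was not seen, as cell cycle and neural progenitor genes had a median of 0.078 against 0.11 for all genes and camera called neither list higher, but against water controls 15 of 56 cell cycle genes were higher and 0 lower. No measured stage of the embryos is given, and a partial mixing of samples was not tested.

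EE2 arrays of one replicate letter moved together. Same-letter pairs on different slides, only 4 and all of letters B or D, had a median correlation of deviations of 0.52. It was 0.41 for same-letter pairs on a shared slide and -0.25 for different letters, which the centring of each group lowers. The 0.52 argues against differences between single slides as the whole cause. Differences between sets of slides stay open, as letters A and B lay on other slides than C and D. A batch of embryos or a handling day that a letter may mark stays open, as the labels do not say what letters stand for.

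Other splits of the same arrays into groups of 4 were counted for each test, 35 where 2 groups were compared and 100 drawn for differences between compounds. In 1 of 35 splits, the real one, the count was as large for bisphenol A EC20 (288, highest other 2) and EC10 (357, 1), methylparaben EC20 (3590, 5) and EC10 (2186, 3). The same held for flutamide EC10 (3, 0), propanil EC20 (143, 1) and EC20 against EC10 (120, 2), and prochloraz EC20 (211, 1) and EC10 (116, 1). At flutamide EC10 the slide block left 0 genes, but only 2 slides held both flutamide and control arrays, so that block has little power. Chance stays open there. For the others these splits, which ignore the slides, argue against chance but do not exclude it. A share of 1 in 35 is the smallest that these splits can give, and shares were not adjusted over the comparisons. Each propanil slide held both groups, and of the 8 splits that part every slide only the real one reached the count at EC20 and between concentrations (highest other 0 in both), too few for a share under 0.05. For methylparaben EC20 against EC10 also 1 of 35 splits reached the count (1, highest other 0), but that gene lost its call without each of the 12 arrays and with either block, so chance stays open there. For propanil against linuron at EC20 3 of 100 drawn splits gave as many (4837, highest other 6822), and with exposed and control exchanged only within slides 1 of 128 did (highest other 4532; with the slide block 1 of 128, 6965, highest other 6684). Other groupings came close, so the size of the count says little. Some of the exchanges within slides left the linuron arrays in their real groups, and chance stays open for linuron alone. These splits therefore do not exclude chance for the difference.

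Chance cannot be excluded for linuron at EC20 (6726, 2 of 35 splits, highest other 6779) and EC10 (1800, 2 of 35, highest other 6456). In both the other split put replicate C of the exposed group together with solvent controls A, B and C, and at EC10 its several times larger count points to a structure of the samples. These splits ignore the slides, each of which held both groups: of the 8 splits that part every slide only the real one reached the count at EC20 (highest other 34, or 20 with the slide block, where the real one gave 8757) and at EC10 (highest other 0, with the block 4914 and 0), but 8 are too few for a share under 0.05. Nor can it be for EE2 EC20 (12, 3 of 35, highest other 2649) or flutamide EC20 (2, 2 of 35, highest other 6858). There, splitting letters A and B from C and D called far more genes, which points to a structure of the samples by letter or by slide. Letters A and B lay on other slides than C and D, so letters and sets of slides cannot be told apart. For propanil against linuron at EC10 (511, 6 of 100, highest other 2471; within slides 12 of 128, highest other 1826), propanil against flutamide at EC20 (14, 6 of 100, highest other 5961) and at EC10 (1, 7 of 100, highest other 1) it cannot be excluded either. The counts of 0 were matched by 35 of 35 splits: EE2 EC20 against EC10 (highest other 387), bisphenol A (0), linuron (28) and prochloraz (1) EC20 against EC10, propanil EC10 (1), and solvent against water for propanil (1933) and linuron (1812). Where letters paired the samples, the real split was also compared with the 8 splits that part all 4 letters, too few for a share under 0.05. Among these only the real split reached the count for EE2 EC20 (12, highest other 0), EE2 EC10 (8, highest other 0) and flutamide EC20 against EC10 (3, highest other 0), while EE2 EC20 against EC10 and propanil solvent against water gave 0 in 8 of 8. Over all 35 splits, 1 reached the count for EE2 EC10 (highest other 0) and 1 for flutamide EC20 against EC10 (highest other 1).

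The share of probes well above background in flutamide EC20 D stood below its group (gap share 0.943) and the 75th percentile of linuron water control B above (0.953). In EE2 experiments these arrays stood apart: slc5a1 in EC20 D above (0.893), fkbp5 in EC20 B below (0.959) and in solvent control B above (0.903), gcga in EC20 A below (0.847), ctrl in EC10 D below (0.880), vtg1 in solvent control C above (0.894), cyp1a in EC20 D above (0.948), kcnj1a.2 in solvent control A below (0.888) and marco in EC20 D below (0.835). With bisphenol A they were ugt1a1 (0.885) and soat2 (0.912) in water control A below, hsp70l in water control B below (0.841), marco in water control C above (0.914) and arf4b in EC20 B below (0.837). With methylparaben, water control B had col10a1a (0.897), fgb (0.850) and fkbp5 (0.951) above and cyp19a1b below (0.941), and EC10 B had vtg1 (0.956), vtna (0.872) and fgb (0.984) below. Also with methylparaben, isg15 in water control C (0.898), f2r2.1 in EC20 A (0.904) and dnajb1a in EC20 D (0.847) stood above, and esr1 in EC10 C below (0.848). With flutamide, hsp70l in EC10 C stood below (0.946) and ugt1a1 in EC20 D above (0.870). Propanil arrays standing above were EC10 D for lgals3bp.3 (0.906) and hadhaa (0.858), EC10 C for cyp19a1b (0.832), solvent control D for sspn (0.859), EC20 D for aqp8a.1 (0.95), EC20 C for ocstamp (0.893) and solvent control A for pnp4b (0.870). In linuron EC20 C, casq2 (0.871), actc1b (0.906), atp5pd (0.845), tnni2a.4 (0.839) and acta1a (0.837) stood above the group and ftr27 below (0.893), while solvent control D had atp5pd (0.962) and agt (0.868) below and solvent control B marco below (0.846). With prochloraz, tcap in EC20 A (0.866) and water control B (0.852), klf3 in EC10 C (0.837), znf395b in EC10 A (0.830) and nfil3-6 in water control A (0.854) stood below. Above were trim63a in EC10 C (0.884), znf395b in EC20 C (0.935) and water control D (0.833), and uqcrb in water control A (0.839).

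Responses that differed between compounds in limma's test were, for propanil less linuron at EC20, casq2 3.73, actc1b 3.5, sspn 3.41, acta1a 3.39, aqp8a.1 3.29, ankar -3.74, elmod1 -3.32, ftr27 -3.06, blnk -2.96 and fzd3b -2.88. For propanil less flutamide at EC20 they were fads2 1.87, kcnj1a.2 1.35, naga 0.95, ms4a17a.6 -2.01, c1qb -1.49, lgals3bp.1 -1.19 and lgals3bp.3 -1.14, of which normexp kept 0 calls and turned ms4a17a.6 (0.85), c1qb (0.50) and lgals3bp.3 (0.0823). In all 4837 and 511 genes differed between propanil and linuron, and 14 and 1 between propanil and flutamide, at EC20 and EC10.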

How the results depend on the processing

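Median scaling, normexp without spots of high local background, and EE2 and flutamide in one fit with a slide block were chosen after seeing the data; the other settings were planned. Scan day was not run as a block, since no experiment was scanned on more than 1 day. Where no reason is given the cause was not tested. Arrays limit what can be read near background, where 63.8 to 82.4 percent of probes were well above it. Over the named genes, 445 results kept their direction and their side of the threshold with every probe tested, 433 with quantile scaling, 431 with the series values, 426 with median scaling, 416 with the replicate block, 415 with the slide block, 404 with no filter, 396 with normexp without spots of high local background, 387 with all arrays in one fit and 317 with normexp. With normexp 108 fell short of the threshold and 16 turned sign. On 8 arrays a few spots of very high local background (up to 65294, against 55 to 1175.5 on the other 80) narrowed the log2 interquartile range of normexp values to 1.01 to 2.72 from 3.39 to 4.0 without these spots. Normexp moved the median of all genes by over 0.1 in EE2 EC20 (0.14), EC10 (-0.22) and between them (0.31), flutamide EC20 (-0.20), EC10 (0.28) and between them (-0.48), methylparaben EC20 (0.19) and between its concentrations (0.15), propanil EC20 (0.19) and between its concentrations (0.19), linuron EC10 (0.24) and between its concentrations (-0.20), propanil against linuron (0.19 at EC20, -0.31 at EC10) and against flutamide (0.43 and -0.30; 0.11 at EC10 without the spots).

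Counts that moved by over 1.5 times are given next by setting, against these main counts: EE2 EC20 12 and EC10 8, bisphenol A 288 and 357, methylparaben 3590 and 2186 (1 between concentrations), flutamide 2 and 3 (3 between), propanil 143 and 0 (120 between), linuron 6726 and 1800 (0 between), prochloraz 211 and 116, propanil against linuron 4837 and 511, propanil against flutamide 14 and 1. Normexp gave EE2 2 and 1, bisphenol A 130 and 125, methylparaben 441, 202 and 0 between concentrations, flutamide 0, 0 and 0 between concentrations, propanil EC20 17 and 7 between concentrations, linuron 749 and 3, propanil against linuron 295 and 0, and propanil against flutamide 0 and 0. Normexp without spots of high local background gave bisphenol A 186 and 183, flutamide 0, 1 and 1 between concentrations, linuron 12605 and 5198, and propanil against linuron 11141 and 1126. All arrays in one fit gave EE2 102 and 41, flutamide 0, 10 and 18 between concentrations, propanil EC20 46 and 40 between concentrations, linuron EC10 6678, 126 between concentrations and 1123 for solvent against water, prochloraz 117 and 55, propanil against linuron at EC10 2053, and propanil against flutamide 9 and 2. No filter gave EE2 EC20 6, bisphenol A 170 and 188, methylparaben EC10 1410 and 0 between concentrations, flutamide EC20 0, linuron EC10 39, and propanil against linuron at EC10 61. Every probe tested gave EE2 EC20 21, methylparaben 0 between concentrations, and propanil against flutamide at EC10 3. Median scaling gave methylparaben 0 between concentrations, flutamide EC20 0, propanil EC20 90 and 66 between concentrations, linuron EC10 1064, and propanil against linuron at EC10 81. Quantile scaling gave flutamide EC20 0 and propanil against linuron at EC10 826. Series values gave EE2 6 and 4, flutamide EC20 0, propanil solvent against water 1, propanil against linuron at EC10 978, and propanil against flutamide 26 and 3. The slide block gave EE2 2 and 1, methylparaben 0 between concentrations, flutamide 0 and 0, linuron EC10 4914, prochloraz EC10 72, propanil against linuron at EC10 2510, and propanil against flutamide at EC20 9. One fit of EE2 and flutamide with a slide block gave EE2 26 and 13, and flutamide EC20 1 and 6 between concentrations. Propanil EC20 gave 385 with pooled controls and 502 with the water reference, where EC10 gave 1, and linuron EC10 gave 560 and 2. Genes shared by at least 2 compounds numbered 393 at EC10 in place of EC20, against 921.

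With the replicate letter as a block, among comparisons where letters paired the samples, the calls of agt and fkbp5 with EE2 at EC20 ended. No gene count moved by over 1.5 times there, and no other call of the named genes ended. The lists past the threshold with EE2 went from 5 to 6 at EC20 and from 10 to 12 at EC10, with the earlier ones kept. In linuron each letter is also a slide, and same-letter deviations had a median r of 0.22 against -0.08 for other pairs, with 17 of 24 over the limit of 0.1, so the letter block there is the slide block and EC10 gave 4914. In the other comparisons not every same-letter pair passed that limit: bisphenol A EC10 gave 220, methylparaben 0 between concentrations, flutamide EC20 0, prochloraz EC10 74, propanil against linuron at EC10 1998, and propanil against flutamide 23 and 2. Of the arrays, 10 of 12 correlated best with their own letter in EE2, 4 of 12 in bisphenol A, methylparaben and prochloraz, 6 of 12 in flutamide, 9 of 16 in propanil and 10 of 16 in linuron.

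Of the lists, 133 passed, 0 with an estimated correlation, 66 with fry (which tests whether genes move one way, not against other genes), 213 with normexp, 150 without the spots, 128 with quantile scaling and 135 with either block. Directions that reversed were, with normexp, npas4a (0.0842) and gzma (0.13) with bisphenol A (0.00415 and 0.0484 without the spots), f2r2.1 (0.23), alpi.2 (0.0349), gvin1l2 (0.0405), crygm5 (0.24) and hspb15 (0.12) with methylparaben EC20, and ms4a17a.6 (0.34) and neurog3 (0.43) with propanil EC20. Further reversals with normexp were rnasel3 (0.11), mylk3 (0.21), ecrg4a (0.19) and gata4 (0.31) with linuron EC10, and ms4a17a.6 (0.85), c1qb (0.50) and lgals3bp.3 (0.0823) between propanil and flutamide. Without the spots ocstamp reversed with linuron EC20 (0.26). List medians whose test direction reversed were ribosomal proteins with linuron EC20 (-0.0919, quantile scaling) and, with normexp, the unfolded protein response with methylparaben (-0.0579) and propanil (0.0277), germ cells (-0.35), cell cycle (0.0339) and ribosomal proteins (0.0370) with flutamide, and Nrf2 targets (0.0646) and hypoxia genes (0.0493) with propanil, all at EC20.

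Leaving out 1 array at a time, counts ran from 6 to 12 for EE2 EC20, 1 to 10 for EC10 and 0 to 0 between them, 155 to 256 and 132 to 379 for bisphenol A EC20 and EC10 and 0 to 1 between them, and 2071 to 4697 and 1225 to 3027 for methylparaben and 0 to 0 between its concentrations. They ran from 0 to 1 and 3 to 4 for flutamide and 3 to 5 between its concentrations, 71 to 152 for propanil EC20, 0 to 0 for EC10 and for solvent against water, and 51 to 128 between concentrations. For linuron they ran from 3382 to 8819 and 1 to 6592, 0 to 5 between concentrations and 0 to 1184 for solvent against water, and for prochloraz 125 to 324 and 64 to 112, and 0 to 1 between concentrations. Differences ran from 3165 to 7398 and 5 to 4206 for propanil against linuron, and 11 to 22 and 1 to 2 for propanil against flutamide.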

Other observations

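No test in this part was chosen to explain a result; the values were picked after the results were seen.

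Pigment cell and skeletal matrix genes were also lower with linuron at EC20 than in solvent controls. Of 26 genes of melanophores and other pigment cells 10 fell and 2 rose (14 and 2 when adjusted over the list alone), with a median of -0.52 (limma camera, adjusted p = 1.11e-05; adjusted p = 0.467 with an estimated correlation) and -0.74 to -0.13 within slides. Of 29 notochord, cartilage and matrix genes 14 fell and 1 rose (16 and 1 when adjusted over the list alone), with a median of -0.57 (adjusted p = 1.3e-07; adjusted p = 0.467 with an estimated correlation) and -1.0 to -0.19 within slides. Of 29 erythroid genes 7 fell with linuron and 1 rose, also when adjusted over the list alone, and the median was -0.50 (adjusted p = 0.000647; adjusted p = 0.616 with an estimated correlation), though -0.77 to 0.18 within slides. Against water controls the linuron medians were smaller in size or turned: -0.18 for pigment cells (7 lower, 2 higher), -0.31 for matrix (9 lower) and 0.12 for erythroid genes (2 lower, 1 higher), so the erythroid fall was seen only against solvent controls. With propanil at EC20 1 of 29 erythroid genes rose and the median was 0.16 (adjusted p = 3.31e-07; adjusted p = 0.278 with an estimated correlation) and 0.08 to 0.23 within slides. No difference between the herbicides was tested for this list. The slide-block medians equalled those given, since each slide held every group of its experiment.

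Pancreas and gut genes were lower with methylparaben at EC20, 9 of 21 with 3 higher (10 and 3 when adjusted over the list alone). Their median was -0.25 (adjusted p = 0.0182; adjusted p = 0.432 with an estimated correlation), -0.25 with the slide block and -0.28 to -0.14 within slides. ins was lower with EE2 (-1.31 at EC20, -1.45 at EC10) and with flutamide at EC10 (-1.61), each against the same 4 control arrays, so these are not independent results. With bisphenol A the vitellogenin and estrogen response list had 2 of 9 genes higher, also when adjusted over the list alone, and a median of 0.22 (adjusted p = 0.00262; adjusted p = 0.291 with an estimated correlation), 0.23 with the slide block and 0.07 to 0.43 within slides. With methylparaben 3 of 9 were higher, also when adjusted over the list alone, with a median of 0.20 (adjusted p = 0.0424; adjusted p = 0.525 with an estimated correlation), 0.18 with the slide block and 0.15 to 0.26 within slides.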
